A study of Mus musculus with 5 samples.

How the data were processed

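RNA was profiled in sections of embryonic day 14.5 mouse knees by GeoMx digital spatial profiling. In this assay, barcoded probes are hybridised to a tissue section, regions of interest are drawn on the stained image, and the barcodes released by light from each region are sequenced. Per the labels, tissue was fixed in formalin and embedded in paraffin, the Mouse Whole Transcriptome Atlas probe set was used, and the sections were stained for Sox9 protein and for DNA so that regions could be chosen by morphology and marker. The chondrocyte factor Sox9 was therefore part of the choice of regions, and its transcript is no finding between region types. Both genotypes carry the Prrx1-Cre driver, which is active in limb bud mesenchyme. The GOF genotype also carries a gain-of-function allele of Pdgfra, the receptor for platelet-derived growth factor, and the control genotype has the driver alone. There were 2 animals per genotype, and the labels put all samples in a single batch. A no-template control sample has no column in the table and was not analysed here.

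The deposited values are signal on a linear scale, counts per target that the authors scaled in each region to a common upper quartile over all targets without a target filter, per the file headers. Each column holds 1 region of interest, and the header ties it to an animal by its scan name and to a region type by its tags. The upper quartile was 10.9 in every region. Within a column, 99.98% of the values were whole multiples of a single step, within a tolerance of 0.01 of a count, so whole counts could be recovered. The smallest recovered count was 1 and no value was 0. A total of 4 targets, each read by several probes, were not whole in most regions. Seurat and the genome build mm10 are named in the submitters' processing notes, with no role given, and the counting pipeline and its version are not given in the sources used here.

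The table holds 179 regions and 19347 targets, of which 1 is the negative probe, which measures background. The other 19346 targets were tested. The headers mark 5 targets, Pdgfra, Col2a1, Col1a1, Sox9 and Gdf5, as custom additions to the probe set. Recovered counts summed to between 55470 and 617053 per region, with a median of 217175. The negative probe had a median value of 2.81, with a lowest value of 1.72 and a highest value of 4.29. Values of a few units therefore lie close to background, and fold changes of such targets are understated.

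Region types were taken from the tags, whose meaning no label defines. They were border-zone cartilage, inter-joint perichondrium, inter-joint space (tagged as Sox9-low interzone), fusion (tagged as Sox9-high interzone and present in GOF animals alone), and a cartilage and a mesenchyme region that the tags call controls and that are named reference cartilage and reference mesenchyme here. Each reference type rests on 1 region per animal. Of the 17 fusion regions, 11 also carry the general interzone tag, as do perichondrium regions, 2 and 3 in control replicates 1 and 2 and 2 and 0 in GOF replicates 1 and 2. The replicate is the animal, so log2(value + 1) was averaged over the regions of each animal and type. This gave 22 values in 11 combinations of genotype and region type.

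The averages were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend), with the animal as a random block whose estimated correlation was 0.02577, 11 residual degrees of freedom and a prior of 9.95. P values were adjusted by the Benjamini-Hochberg method within each contrast, and an adjusted p below 0.05 counted as a call. Fold changes are on the log2(value + 1) scale, with standard errors (SE) from the fit. The contrasts were GOF minus control within each of the 5 region types that both genotypes have, the differences of those effects between the 3 joint region types (border-zone cartilage, inter-joint perichondrium and inter-joint space), and each control region type against the mean of the other control types. The genotype effect over all region types used 1 mean per animal. Comparisons of the fusion regions with control inter-joint space, GOF inter-joint space and GOF border-zone cartilage were added after the region tags had been read. With 2 animals per genotype, no permutation of animals can reach a p of 0.05. The limma p values of single targets rest on the spread that limma pools over region types and targets. The p values of gene lists take targets as units, so they do not measure the spread between animals.

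Gene lists were fixed before the data were examined. The 26 lists cover PDGF ligands and receptors, receptor tyrosine kinase feedback and MAPK targets, interferon response, chondrocyte identity and cartilage matrix, prehypertrophic and hypertrophic chondrocyte, interzone and articular progenitor, tendon and ligament, fibrous collagen and fibroblast matrix, connective tissue fibroblast progenitor, synovial lining, contractile and myofibroblast, osteoblast, proliferation, BMP and TGF-beta targets, Wnt targets and regulators, hedgehog targets, matrix proteases and inhibitors, skeletal muscle, endothelium, pericyte and vascular smooth muscle, erythroid, macrophage and osteoclast, Schwann cell and neuron, surface ectoderm and keratinocyte, hypoxia and glycolysis, and fixation and stress response. List shifts were tested with cameraPR of limma on the moderated statistics at a preset correlation of 0.01, adjusted over the 26 lists within a contrast. The alternative used a correlation estimated from the residuals. Some lists share members, for example Egr1, which the MAPK, tendon and stress lists all hold. The Wnt list holds antagonists of the pathway, such as Sfrp2 and Frzb, beside its targets. The hedgehog list holds co-receptors and the repressor gene Gli3 beside the readouts Gli1 and Ptch1. Shifts of these lists therefore do not give the direction of pathway output.

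Named genes followed a rule fixed before the data were examined. It took Pdgfra first, then up to 10 higher and 10 lower called genes by absolute log2 fold change whose animal means do not overlap between the groups, without predicted gene models. Where fewer than 10 genes passed, the list was filled to 10 by the smallest unadjusted p, given as values only. Up to 4 members of each gene list were added, and the control region contrasts took up to 5 genes each way. Further genes come from a fit without the reference types, below.

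Alternatives set beforehand were pseudocounts of 0.1 and 5, the upper part of the targets by mean value, quantile normalization, median centring, eBayes without trend and robust, the replicate number as a block, each region type fitted alone, regions as units with the animal as a block, control animals alone, an estimated list correlation, and leaving out each animal. After the data were seen, further alternatives were added. They were a fit without the reference types (called the joint-region fit), weights by the number of regions, subtraction of the negative probe, perichondrium without its interzone-tagged regions, an estimated list correlation floored at 0, and the edgeR 4.0.16 quasi-likelihood test on recovered counts summed per animal and region type. The joint-region fit was added because the reference types, with 1 region per animal, share 1 estimate of the spread with types averaged over 7 to 19 regions per animal. It had 7 residual degrees of freedom, a prior of 33.19 and a correlation within animals of 0.1414. It leaves each fold change within a joint region type as it was and changes its error. Genes named from it were the 20 largest rises and 20 largest falls among its calls, or called members of the fixed lists.

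The fits were tested on simulated counts for the 19346 targets, with 200 targets changed, an extra-Poisson spread of 0.01646 and a between-animal SD of 0.1067 on the log2 scale. For inter-joint space, the fit of all types recovered 0% of the 1.5-fold changes, 4.48% of the 2-fold changes and 63.6% of the 4-fold changes, with 0 false calls. The joint-region fit recovered 29.9%, 79.1% and 98.5% for the same contrast (20, 53 and 65 targets), with 21 false calls. The share of false calls was therefore larger than the adjusted p threshold allows. Calls of the joint-region fit in inter-joint space may hold more false ones than their adjusted p values state. In border-zone cartilage and inter-joint perichondrium the joint-region fit made 1 and 2 false calls. For reference cartilage the fit of all types made 1224 false calls, and for reference mesenchyme it made 172. The raised list of the simulation passed with an adjusted p of 1.22e-170, and 0 of the 25 unchanged lists passed. Simulated targets varied independently and the unchanged lists were drawn at random. The simulation therefore cannot show false calls of lists whose members move together. The values were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, the data.table package (version 1.17.8) was used in R, and plots were drawn with matplotlib 3.10.9. Gene positions are those of GRCm38, the assembly that mm10 names.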

Results

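The series measured RNA in 179 regions of knee sections from 4 mouse embryos at E14.5. By its title it concerns PDGF receptor alpha signaling in the differentiation of cartilage and fibrous tissue as synovial joints form. Control replicates 1 and 2 gave 46 and 40 regions, and GOF replicates 1 and 2 gave 47 and 46. Border-zone cartilage was sampled in 16 and 13 control regions and in 15 and 16 GOF regions. Inter-joint perichondrium was sampled in 19 and 16 control regions and in 14 and 12 GOF regions. Inter-joint space was sampled in 9 and 9 control regions and in 7 and 8 GOF regions. The fusion type was drawn in GOF animals alone, in 9 and 8 regions. The median total count per region was 203778 and 250055 in control replicates 1 and 2 and 242106 and 176310 in GOF replicates 1 and 2. The median negative probe value was 3.06 and 2.76 in the controls and 2.97 and 2.29 in the GOF animals, so background was lowest in GOF replicate 2. All values are means over 2 animals per genotype, with the SD between animals (n = 2), and adjusted p values are from limma unless edgeR is named.

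In control knees, cartilage matrix genes were higher in the cartilage regions, joint interzone genes were higher in inter-joint space, and muscle genes were higher in reference mesenchyme. Border-zone cartilage was higher than the mean of the other control types for the cartilage matrix genes Matn4 (log2 difference 2.23, adjusted p = 6.1e-06), Hapln1 (2.07) and Matn3 (2.03). Of the 27 measured members of the chondrocyte list, 19 were called higher there, with a median log2 difference of 1.38. Inter-joint space was higher for Gdf5, the growth factor that marks the forming joint (2.80, adjusted p = 2e-06), and for Sulf1 (2.91), Pamr1 (2.65), Lrrc17 (2.60) and Sfrp2, a secreted Wnt antagonist (2.58). It was lower for Col2a1 (-1.76), Col9a1 (-1.86), Susd5 (-1.79) and Thbs1 (-1.92). Of the 28 interzone members 12 were called higher in inter-joint space and 1 lower, and of the 27 chondrocyte members 19 were called lower and 0 higher. Inter-joint space is tagged Sox9-low, so differences in cartilage genes that vary with Sox9 are partly set by how the regions were drawn. Inter-joint perichondrium was higher for Sulf1 (2.10), Sfrp2 (1.71), Dkk3 (1.71), Tgfbi (1.59) and Barx1 (1.52), and 6 of the 28 interzone members were called higher. Reference mesenchyme was higher for the skeletal muscle genes Acta1 (5.36), Mylpf (5.10) and Myh3 (4.97), and 18 of the 22 measured skeletal muscle members were called higher. Reference cartilage was higher for Matn1 (4.20), Epyc (4.07) and Col2a1 (3.35). Calls numbered 75 for border-zone cartilage, 36 for inter-joint perichondrium, 291 for inter-joint space, 2173 for reference cartilage and 1268 for reference mesenchyme. The reference types rest on 1 region per animal and share their spread with types averaged over more regions, a setting that gave 1224 and 172 false calls in a simulation of their genotype contrasts. With the control animals fitted alone, perichondrium had 8 calls and reference mesenchyme 777.

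Pdgfra transcript did not differ by genotype past the threshold in any region type. The gene lies on chromosome 5 at 75151322 to 75198206. Its level in border-zone cartilage was 37.5 ± 4.1 in controls and 49.0 ± 0.55 in GOF animals (log2 fold change 0.31, SE 0.24). In inter-joint perichondrium it was 73.5 ± 6.7 and 85.4 ± 3.2 (0.21, SE 0.24), and in inter-joint space 101 ± 8.4 and 93.1 ± 11 (-0.13, SE 0.24). Over all region types the Pdgfra difference was 0.22 with an adjusted p of 0.782. The labels do not say how the allele was made, and the probe reads total Pdgfra transcript, so its level does not check the genotype. The PDGF ligand and receptor list did not pass in any of the genotype contrasts, and its adjusted p over all region types was 0.0665. The target for the red fluorescent reporters mCherry and tdTomato (mCherry/tdTomato in the table) separated the genotypes. In inter-joint space it read 15.5 ± 1.1 in controls and 398 ± 97 in GOF animals, 24.8-fold higher (adjusted p = 7.25e-11). It was also called in border-zone cartilage (19.0-fold) and in inter-joint perichondrium (22.0-fold). Which animals carried a reporter is not given in the sources used here.

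In inter-joint space, genes of receptor tyrosine kinase signaling were higher in GOF animals, and genes of the joint interzone, of fibrous matrix and of the combined BMP and TGF-beta list were lower. Sox9-high interzone was tagged apart as fusion in GOF knees alone, so the space regions of the genotypes may not cover the same tissue. Egr1, an immediate early transcription factor induced by MAPK signaling, rose from 16.7 ± 0.074 to 112 ± 55, a 6.26-fold difference (log2 fold change 2.65, SE 0.40, adjusted p = 0.00861). Gdf5 fell from 75.2 ± 7.4 to 21.9 ± 6.2, 4.09-fold lower (-2.03, SE 0.34, adjusted p = 0.0148). Lgr5, a receptor for R-spondins, fell from 28.1 ± 1.6 to 9.0 ± 0.46, 3.02-fold lower (-1.59, SE 0.27, adjusted p = 0.0155). Fbn2, which encodes the microfibril protein fibrillin 2, fell from 201 ± 7.8 to 68.4 ± 6.2, 3.03-fold lower (adjusted p = 0.00478). Postn, which encodes the matricellular protein periostin, fell from 150 ± 9.2 to 57.7 ± 14, 2.84-fold lower (adjusted p = 0.0442). Egr1 lies on chromosome 18 at 34861207 to 34864956, Gdf5 on chromosome 2 at 155941023 to 155945367, Lgr5 on chromosome 10 at 115450314 to 115587780 and Postn on chromosome 3 at 54359267 to 54391041.

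Among 19346 targets, 20 were called in inter-joint space, 6 higher and 14 lower, and 409 had an unadjusted p below 0.05. Besides the reporter and Egr1, the higher calls were Tcim (1.84), Rtl3 (1.76), the cyclin gene Ccnd2 (1.19) and the imprinted gene Peg10 (0.83). Other lower calls included the semaphorin receptor gene Plxna4 (-1.79), the MAPK phosphatase gene Dusp1 (-1.72), Prss35 (-1.69), the fibroblast protease gene Fap (-1.58), the BMP target Id3 (-1.55), the growth factor gene Tgfb2 (-1.49) and the collagen gene Col5a2 (-1.12). Without control replicate 1 there was 1 call, which was among the 20. There were 3 without control replicate 2 (2 among the 20), 2 without GOF replicate 1 (2 among the 20) and 6 without GOF replicate 2 (5 among the 20). In the joint-region fit 521 targets were called, 212 higher and 309 lower, the 20 included, and edgeR called 360. The simulation gave the joint-region fit a larger share of false calls in inter-joint space than the threshold allows. Its 521 calls are therefore less certain than their adjusted p values state.

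In the joint-region fit, which was chosen after the data were seen, the further rises in inter-joint space included feedback regulators of receptor tyrosine kinase signaling. Spry2 rose from 17.5 ± 3.6 to 42.6 ± 17 (log2 fold change 1.22, SE 0.17, adjusted p = 2.4e-06), and Dusp6, an ERK phosphatase gene, from 6.84 ± 0.47 to 14.1 ± 0.13 (0.94). Egr2 (1.07), Nr4a1 (1.09), Nr4a2 (1.17), Spry1 (0.95) and the Egr corepressor gene Nab2 (0.95) also rose. The joint-associated ligand gene Wnt4 rose by 1.33. Further falls were Pamr1 from 74.6 ± 1.8 to 13.5 ± 0.60 (-2.58), the serine protease gene Htra1 (-1.78), Dkk3 (-1.68), Tgfbi (-1.54), Col8a2 (-1.53) and the cross-linking enzyme gene Lox (-1.42). The transcription factor gene Osr2 (-1.13), Gdf6 (-0.93) and the collagen gene Col22a1 (-1.17) fell as well.

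**Figure D1:**
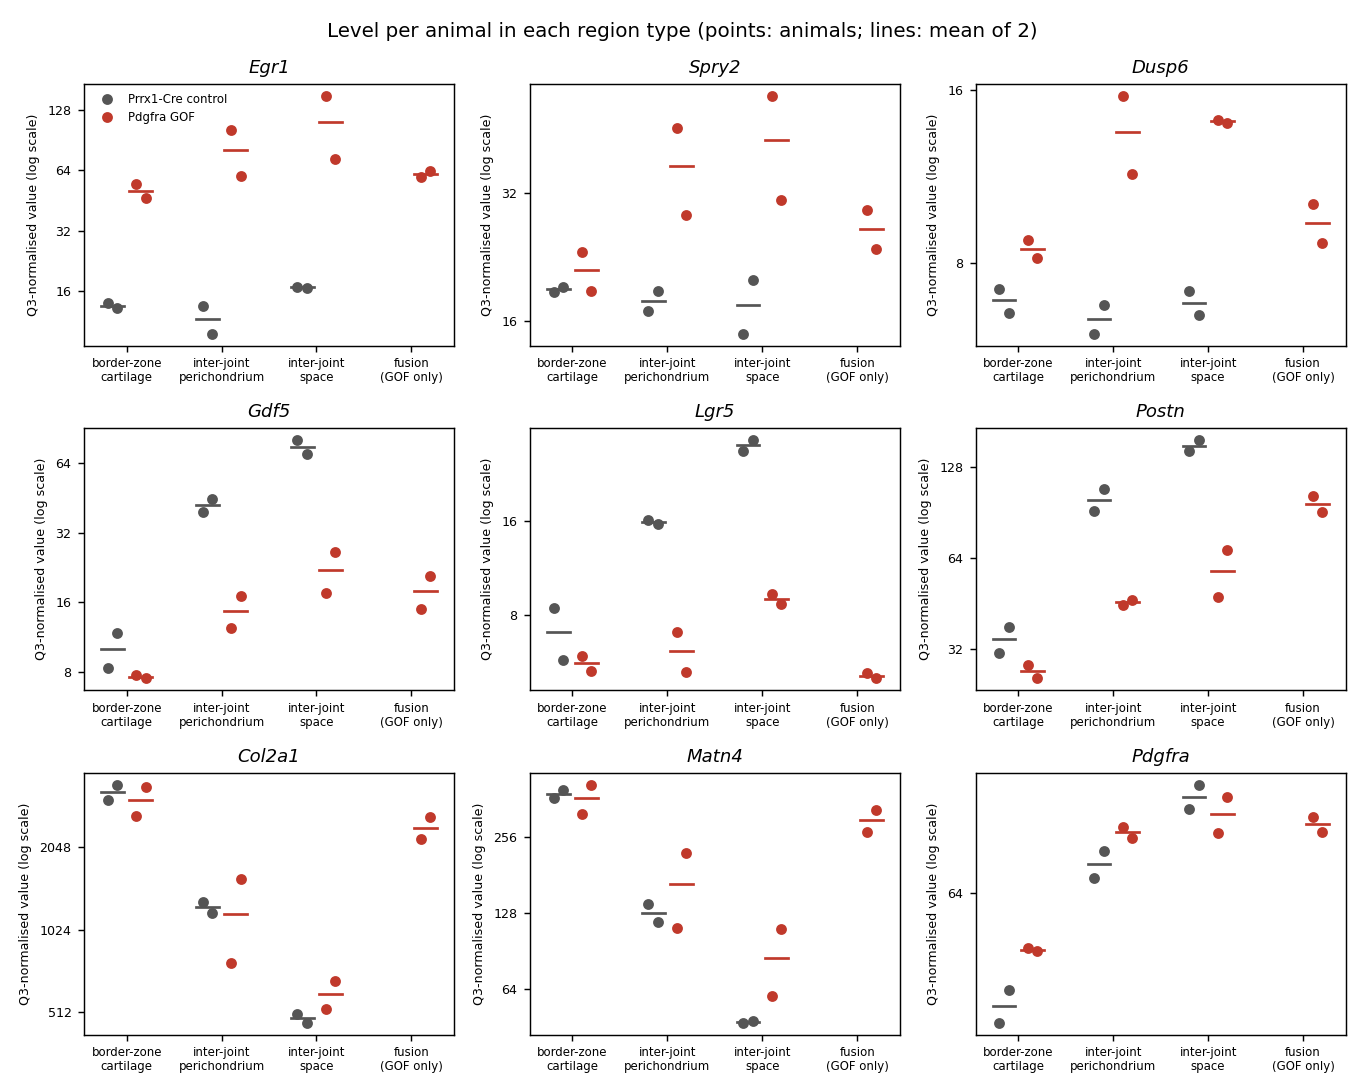
Levels of 9 genes by region type, with 1 point per animal (mean over its regions) and a line at the mean of the 2 animals of a genotype, on a log2 axis of the Q3-normalised value. Egr1 in inter-joint space reads 16.7 in controls and 112 in GOF animals, and Gdf5 reads 75.2 and 21.9.

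The gene lists moved as groups in inter-joint space. Of the 26 measured MAPK targets, 21 had positive estimates with a median log2 fold change of 0.52, and the list passed (adjusted p = 3.36e-22, and adjusted p = 1.60e-10 with an estimated correlation). Of its members 1 was called over all targets and 8 higher when adjusted over the list alone, and the joint-region fit called 12 higher and 1, the stress-induced gene Ier3, lower. The fibrous matrix list had a median of -0.67, with 30 of 33 members negative (adjusted p = 1.44e-40, 3.74e-11 with an estimated correlation). Its called members were Fbn2, Postn and Col5a2, and 16 members fell and 1 rose when adjusted over the list alone. The interzone list had a median of -0.57 (adjusted p = 2.53e-15, 4.20e-18 with an estimated correlation). Called lower were Gdf5 and Lgr5, and adjusted over the list alone 11 fell while Wnt4 and Dcx rose. The tendon list (-0.43, adjusted p = 2.39e-06) had 21 of 26 members negative, with 1 called higher, Egr1, and adjusted over the list alone 4 lower. The BMP and TGF-beta list (-0.36, adjusted p = 1.78e-09) had 2 called lower, Id3 and Tgfb2, and 3 when adjusted over the list alone. With an estimated correlation the adjusted p was 0.00554 for the tendon list and 4.56e-07 for the BMP and TGF-beta list.

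Smaller shifts in inter-joint space concerned cartilage and vessels. The chondrocyte list had a median of 0.17 (adjusted p = 0.000108) and lost its call with an adjusted p of 0.227 with an estimated correlation. No chondrocyte member passed over all targets, and the joint-region fit called Matn4 (0.71), Sox5 (0.67) and Wwp2 (0.54) higher. The prehypertrophic list had a median of 0.11 (adjusted p = 0.0477, 0.00694 with an estimated correlation). The endothelial list had a median of 0.30, with 14 of 14 members positive (adjusted p = 0.000408, 0.00212 with an estimated correlation). Sox18, an endothelial transcription factor gene, read 5.68 ± 0.12 in controls and 11.1 ± 3.0 in GOF animals. The fibroblast progenitor list (-0.07, adjusted p = 0.0340) lost its call with an adjusted p of 0.173 with an estimated correlation. The other 17 lists did not pass, and the lowest adjusted p among them was 0.0534.

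The median log2 fold changes of those 17 lists in inter-joint space were as follows. They were 0.05 for PDGF ligands and receptors (adjusted p = 0.932), -0.02 for the interferon response (0.244), 0.0074 for synovial lining (0.345), -0.10 for contractile genes (0.0534), 0.15 for osteoblast genes (0.0534) and -0.03 for proliferation (0.604). The Wnt list had -0.0035 (0.0670), the hedgehog list -0.06 (0.0719), matrix proteases -0.15 (0.0682), skeletal muscle -0.13 (0.0534) and pericyte genes -0.03 (0.267). Erythroid genes had 0.16 (0.480), macrophage and osteoclast genes -0.04 (0.932), Schwann cell and neuron genes -0.02 (0.892), surface ectoderm genes -0.06 (0.975), hypoxia genes -0.02 (0.892) and the stress list -0.02 (0.0762). The mean was positive, against a negative median, for the interferon (0.06), proliferation (0.0041) and stress (0.17) lists. The test pointed up with negative medians and means for the macrophage, Schwann cell and ectoderm lists. With an estimated correlation the Wnt list had an adjusted p of 0.0170 and the hedgehog list an adjusted p of 0.00505.

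In inter-joint perichondrium, Egr1 rose from 11.6 ± 2.6 to 80.6 ± 29, a 6.51-fold difference (log2 fold change 2.70, SE 0.40, adjusted p = 0.0095). Tcim rose from 6.08 ± 0.31 to 25.8 ± 0.29, 3.63-fold higher (adjusted p = 0.0382). With the reporter these were the 3 calls, and 182 targets had an unadjusted p below 0.05. Without control replicate 1 the number of calls was 1. Values of genes that did not pass were -1.37 for Dusp1, -1.31 for Lgr5, -1.20 for Mn1, -1.07 for Fbn2, -0.94 for Bgn and 1.00 for Smoc2, with an adjusted p of 0.26 for each of the first 4. The joint-region fit called 200 targets, 72 higher and 128 lower, and edgeR called 229. In that fit Lgr5, Fbn2 and Dusp1 fell. Gdf5 fell from 42.1 ± 4.0 to 14.6 ± 3.3 (-1.34), Pamr1 from 29.2 ± 0.74 to 11 ± 0.78 (-1.51), Tgfbi from 142 ± 15 to 53.7 ± 7.9 (-1.48) and Postn from 99.6 ± 11 to 45.6 ± 1.2 (-1.16). Nab2 (1.21), Nr4a1 (1.07), Spry2 (1.01), Dusp6 (0.95), Wnt4 (0.92) and the ETS factor gene Etv5 (0.80) rose.

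The lists that passed in inter-joint perichondrium numbered 9. MAPK targets had a median log2 fold change of 0.40 (adjusted p = 7.33e-27, 2.46e-12 with an estimated correlation), with 1 called and 3 higher when adjusted over the list alone. Fibrous matrix (-0.33, 1.14e-24 and 4.41e-07) had 0 called by limma over all targets and 7 lower when adjusted over the list alone, and the joint-region fit called 9 lower. Interzone genes (-0.28, 1.44e-07 and 8.18e-09) had 0 called over all targets and 4 lower when adjusted over the list alone, namely Dkk3, Ltbp1, Gdf5 and Lgr5. The joint-region fit called 9 interzone members lower and 2, Wnt4 and Dcx, higher. BMP and TGF-beta targets (-0.26, 1.42e-10 and 7.67e-08), tendon genes (-0.31, 3.77e-05 and 0.0153) and contractile genes (-0.16, 0.00188 and 0.0206) were lower. So was the list of Wnt targets and regulators (-0.13, 0.00107 and 1.37e-05), in which the joint-region fit called Dkk3, Sfrp2 and Lgr5 lower. The stress list was higher (0.05, adjusted p = 8.71e-05, 0.00725 with an estimated correlation), and its calls when adjusted over the list alone were Egr1 higher and Jund lower. The hypoxia list (-0.13, adjusted p = 0.0165) lost its call with an adjusted p of 0.391 with an estimated correlation.

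In border-zone cartilage the reporter was the single call, and 65 targets had an unadjusted p below 0.05. Without control replicate 2 there were 2 calls. The lowest adjusted p values that did not pass were for Smoc2, which encodes a matricellular protein (25.8 ± 0.74 in controls and 66.9 ± 1.9 in GOF animals, log2 fold change 1.34, adjusted p = 0.0607), and for the cartilage matrix gene Matn3 (99.6 ± 8.5 and 44.6 ± 9.7, -1.20, adjusted p = 0.169). Further values were 1.89 for Egr1, -1.79 for Serpina3n, -0.89 for Id3, -0.72 for Chad, 0.95 for Tcim, 0.80 for Robo1 and 0.66 for Zfp36l1. The joint-region fit called 41 targets, 26 higher and 15 lower, and edgeR called 31. In that fit Egr1 rose from 13.5 ± 0.50 to 50.6 ± 5.9, and Smoc2, Dcx (0.81), Col26a1 (0.80) and Robo1 rose. Serpina3n fell from 35.5 ± 3.1 to 9.75 ± 0.10, and Matn3, Id3, Ccn2 (-0.80), the BMP antagonist gene Nog (-0.77), Chad and Epyc (-0.65) fell.

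Of the 6 lists that passed in border-zone cartilage, 1 held with an estimated correlation. That list was the BMP and TGF-beta targets, with a median of -0.23 and 16 of 22 members negative (adjusted p = 0.000109, 0.00370 with an estimated correlation). It had 0 members called by limma, over all targets or when adjusted over the list alone, and 3 in the joint-region fit. The chondrocyte list had 23 of 27 members negative (median -0.19, adjusted p = 5.50e-07), and its adjusted p with an estimated correlation was 0.154. Adjusted over the list alone, Matn3 and Chad were lower. The other lists lost their call as well, with an adjusted p with an estimated correlation of 0.0748 for MAPK targets (0.11), 0.0748 for contractile genes (-0.25), 0.130 for proliferation (-0.21) and 0.290 for fibrous matrix (-0.11). Without GOF replicate 1 the chondrocyte list had an adjusted p of 0.981. Its mean t stayed negative at -0.147, and only its position relative to the mean of the other targets turned.

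The reference regions gave 1422 calls in cartilage, 602 higher and 820 lower, and 165 in mesenchyme, 71 higher and 94 lower. The simulation with 200 changed targets gave 1224 and 172 false calls for these contrasts. Fitted alone, reference cartilage had 6 calls and reference mesenchyme 2, and edgeR called 4 and 26. Reference cartilage had 44 calls without GOF replicate 2. Reference mesenchyme had 5 without control replicate 1, 515 without control replicate 2, 568 without GOF replicate 1 and 2 without GOF replicate 2. The reporter was 4.03 and 3.72 higher on the log2 scale in reference cartilage and reference mesenchyme. Log2 values were 1.57 for Egr1 and 2.08 for Smoc2 in reference cartilage, and 1.59 for Dusp6 and -2.02 for Tnmd in reference mesenchyme. None of the 26 lists passed in reference cartilage. In reference mesenchyme 7 did, and those that held with an estimated correlation were MAPK targets (median 0.42), BMP and TGF-beta targets (-0.59), endothelium (0.50) and macrophage and osteoclast (0.34). Those that did not were chondrocyte (-0.31, adjusted p = 0.36 with an estimated correlation), tendon (-0.54, adjusted p = 0.12) and Schwann cell (0.27, adjusted p = 0.14). Quantile normalization changed the split in reference cartilage to 415 higher and 360 lower, and the subtracted negative probe changed it to 862 and 771. In reference mesenchyme median centring gave 107 higher and 61 lower, and the subtracted negative probe 168 and 62.

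Averaged over the 5 region types that both genotypes share, 44 targets were called, 21 higher and 23 lower, and 1337 had an unadjusted p below 0.05. Egr1 rose 4.04-fold (log2 fold change 2.01, SE 0.14, adjusted p = 1.04e-12). Smoc2 (0.96), Dusp6 (0.91), Rgmb, a BMP co-receptor gene (0.86), Tcim (0.85), Plekha4 (0.81), Col26a1 (0.78) and Serpine2, a serine protease inhibitor gene (0.76), rose. Tgfbi fell 2.42-fold (-1.28, SE 0.15, adjusted p = 2.08e-06), and Htra1 (-1.13), Pamr1 (-1.10), Id3 (-1.04), Dkk3 (-0.96), the tendon proteoglycan gene Fmod (-0.87), Gdf5 (-0.87), Ssc5d (-0.85), Lgr5 (-0.83) and Lox (-0.81) fell. The count was 39 without control replicate 1, 54 without control replicate 2, 327 without GOF replicate 1 and 143 without GOF replicate 2. Median centring turned the majority to 29 higher and 21 lower, and the subtracted negative probe to 45 and 27. The count was 319 without the reference types, of which 41 were among the 44, and 354 with edgeR.

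Over all region types 12 lists passed. MAPK targets were higher (median 0.36, adjusted p = 9.73e-23), with 3 called, Egr1, Dusp6 and Phlda1, and 14 higher and 1 lower when adjusted over the list alone. The BMP and TGF-beta list (-0.31, adjusted p = 3.71e-14) had 2 called lower and 7 when adjusted over the list alone. Tendon genes (-0.32, adjusted p = 3.68e-08) had 4 called lower, namely Tgfbi, Fmod, Lox and Bgn, and 11 when adjusted over the list alone. Fibrous matrix (-0.17, adjusted p = 1.61e-07), chondrocyte (-0.20, 0.000157), interzone (-0.14, 0.0012) and Wnt (-0.12, 0.036) lists were lower, and prehypertrophic (0.11, 0.00111) and endothelial (0.17, 0.00111) lists were higher. The chondrocyte list lost its call without GOF replicate 1 (adjusted p = 0.239) and without the reference types (adjusted p = 0.969). In the latter its mean t stayed negative at -0.342, and only its position relative to the mean of the other targets turned. The stress list passed as higher (0.000137), with a mean of 0.18 and a median of -0.0067, and its higher call was Egr1. With an estimated correlation the contractile (-0.12) and osteoblast (0.098) lists lost their calls, with an adjusted p of 0.0598 and an adjusted p of 0.0953.

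Whether the genotype effect differed between region types was tested directly. By limma 0 targets passed for any of the 3 differences, with 120, 21 and 22 at an unadjusted p below 0.05 for inter-joint space minus border-zone cartilage, inter-joint space minus inter-joint perichondrium, and inter-joint perichondrium minus border-zone cartilage. Results of edgeR were not kept for these contrasts. There were 148, 3 and 13 calls in the joint-region fit. For inter-joint space minus border-zone cartilage its calls included Pamr1 (difference of log2 fold changes -1.89), Tgfb2 (-1.69), Gdf5 (-1.65), Osr2 (-1.56), Col5a2 (-1.42) and Lgr5 (-1.21), which changed more negatively in the space, and Rtl3 (1.70), Penk (1.67), Serpina3n (1.53) and Spry2 (1.11), which changed more positively. The 3 called for space minus perichondrium were Osr2 (-1.26), Fjx1 (-1.12) and Pamr1 (-1.07). At list level the interzone genes (-0.63, adjusted p = 6.94e-15) and fibrous matrix genes (-0.47, adjusted p = 1.35e-25) changed more negatively in inter-joint space than in border-zone cartilage. The MAPK (0.34, adjusted p = 6.85e-11) and chondrocyte lists (0.38, adjusted p = 9.33e-15) changed more positively. With an estimated correlation those adjusted p values were 8.74e-18, 4.11e-07, 3.85e-05 and 0.0117.

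The fusion regions of GOF knees carried cartilage transcripts at levels well above those of control inter-joint space. Col2a1, which encodes the main collagen of cartilage, read 486 ± 24 in control inter-joint space, 599 ± 99 in GOF inter-joint space, 2421 ± 312 in fusion regions and 3041 ± 517 in GOF border-zone cartilage. It was 4.92-fold higher in fusion regions than in control inter-joint space (log2 difference 2.30, SE 0.25, adjusted p = 2.41e-05). Matn4 (2.62), Cytl1 (2.43), the Wnt antagonist gene Frzb (2.41), Col9a3 (2.36), Wwp2 (2.22), Col11a2 (2.09), Rtl3 (1.96) and Egr1 (1.91) were also higher. Lower were Pamr1 (-3.15), Tgfbi (-2.60), Fhod3 (-2.58), Lrrc17 (-2.56), Mylk (-2.34), Lgr5 (-2.27), Gdf5 (-2.25), Dusp1 (-2.20), Ssc5d (-2.15) and Sulf1 (-2.09). Gdf5 read 75.2 ± 7.4 in control space and 17.9 ± 4.0 in fusion regions. Pdgfra differed by -0.20 and did not pass. Col2a1 lies on chromosome 15 at 97975602 to 98004724 and Matn4 on chromosome 2 at 164389393 to 164405160. Regions were chosen with Sox9 staining, and the fusion tag goes with high Sox9, so cartilage genes that vary with Sox9 are part of how the regions were drawn.

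Against control inter-joint space 141 targets were called, 79 higher and 62 lower, and 715 had an unadjusted p below 0.05. Quantile normalization turned the majority, to 84 higher and 111 lower. The count lay at 32 and 35 without control replicates 1 and 2, and at 37 and 41 without GOF replicates 1 and 2. Calls numbered 1007 in the joint-region fit and 802 with edgeR. Of the chondrocyte list 17 of 27 members were called higher and 0 lower, 19 when adjusted over the list alone (median 1.5, adjusted p = 1.37e-103, 2.92e-15 with an estimated correlation). Interzone genes were lower (-0.51, adjusted p = 2.05e-17), with 5 called lower and 2, Erg and Thbs1, higher, and 8 lower and 2 higher when adjusted over the list alone. Fibrous matrix was lower (-0.28, adjusted p = 1.22e-08), with Fn1, Col5a1 and Fbn2 called lower and Col16a1 higher, and 11 lower and 1 higher when adjusted over the list alone. MAPK targets were higher (0.30, adjusted p = 1.06e-06), with Egr1 and Etv5 called and 3 when adjusted over the list alone. BMP and TGF-beta targets (-0.23, 3.31e-06), fibroblast progenitor genes (-0.28, 0.00207) and matrix proteases (-0.29, 0.0245) were lower. Proliferation (0.22, 1.50e-05) and prehypertrophic (0.20, 0.0162) lists were higher. The fibroblast progenitor list had an adjusted p of 0.0473 with an estimated correlation, and proliferation had an adjusted p of 0.0364. The hypoxia list (0.16, 0.0322) lost its call with an adjusted p of 0.468 with an estimated correlation.

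Within GOF knees, fusion regions were compared with inter-joint space and 43 targets were called, 34 higher and 9 lower, with 482 at an unadjusted p below 0.05. Cartilage genes were again higher, with Col9a3 4.54-fold (adjusted p = 0.0177), Cnmd (2.09), Col2a1 (1.92), Matn4 (1.91), Frzb (1.78), Wwp2 (1.68), Acan, which encodes aggrecan (1.68), Col11a2 (1.67), Col9a2 (1.63) and Papss2 (1.51). Lower were Khdrbs2 (-1.92), the transcription factor gene Pax9 (-1.86), Ccdc80 (-1.55), Cited2 (-1.48), Lhx9 (-1.29), Fabp5 (-1.29), Egfl6 (-1.14), Tmsb4x (-0.87) and Sox4 (-0.85). Of the chondrocyte list 14 of 27 were called higher, 19 when adjusted over the list alone (median 1.30, adjusted p = 7.39e-99, 2.85e-14 with an estimated correlation). Fibrous matrix was higher as well (0.32, adjusted p = 1.76e-08, 0.0160 with an estimated correlation), with Col1a2 and Col16a1 called, and 4 higher and 1 lower when adjusted over the list alone. Col1a2 read 95.3 ± 38 in GOF inter-joint space and 231 ± 25 in fusion regions. The endothelial list was lower (-0.43, adjusted p = 0.00222, 0.0156 with an estimated correlation). MAPK targets (-0.18), tendon (0.27), proliferation (0.27) and hypoxia (0.24) lists lost their calls with adjusted p values of 0.0755, 0.251, 0.0562 and 0.354 with an estimated correlation. Pdgfra differed by -0.08. The count was 1 without control replicate 1, control replicate 2 or GOF replicate 1, 6 without GOF replicate 2, 885 in the joint-region fit and 419 with edgeR.

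Against GOF border-zone cartilage, fusion regions were higher for Postn (96.4 ± 8.2 against 26.9 ± 1.9, 3.53-fold, adjusted p = 0.0458) and Col5a2 (71.6 ± 1.3 against 32.3 ± 3.9, 2.15-fold, adjusted p = 0.0458). These were the 2 calls, with 147 targets at an unadjusted p below 0.05. Log2 differences that did not pass were 1.41 for Col26a1, 1.14 for Bgn, 1.10 for Col1a2, 1.07 for Col12a1, 0.95 for Ebf3, 0.87 for Fzd8, -1.12 for Matn3 and -1.16 for Lhx9. Pdgfra read 88.6 ± 4.3 in fusion regions and 49.0 ± 0.55 in GOF cartilage (0.91, adjusted p = 0.976), and passed in the joint-region fit with an adjusted p of 5.4e-07. The joint-region fit called 230 targets, 171 higher and 59 lower, and edgeR called 72. Without any 1 animal, with the replicate block, with a pseudocount of 0.1, without trend or with the negative probe subtracted the count was 0.

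At list level, fibrous matrix was higher in fusion regions than in GOF cartilage (median 0.43, adjusted p = 7.93e-47, 1.55e-12 with an estimated correlation), with 2 called and 11 when adjusted over the list alone. Tendon (0.41, adjusted p = 8.21e-18, 3 higher when adjusted over the list alone), interzone (0.23, 2.69e-07) and fibroblast progenitor genes (0.18, 0.000824) were higher, the last 2 lists with 1 member each, Ltbp1 and Igfbp4, higher when adjusted over the list alone. So was the list of Wnt targets and regulators (0.11, 0.0397), in which the joint-region fit called Dkk3, Sfrp2 and Frzb higher. With an estimated correlation these 4 had adjusted p values of 2.18e-07, 1.74e-08, 0.0463 and 0.00608. The chondrocyte list was lower (-0.34, adjusted p = 1.12e-31, 4.81e-05 with an estimated correlation). Its members Matn3, Hapln1, Fgfr3, Susd5 and Chad were lower when adjusted over the list alone. MAPK (0.14), hypoxia (-0.20) and Schwann cell (-0.083) lists lost their calls, with adjusted p values of 0.218, 0.159 and 0.0802 with an estimated correlation.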

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

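The lists were fixed before the data were examined, and the tests below were chosen after the results had been seen, except the mixture that also holds perichondrium. The gene counts without the reference types were added after the data were seen.

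In the list tests, 16 differences of the genotype effect between region types passed. Their adjusted p was below 0.05 with the preset, the estimated and the floored correlation. Each setting takes targets as units, so the spread between animals is not measured. Differences that involve inter-joint space may also reflect that Sox9-high interzone was tagged apart as fusion in GOF knees alone. For inter-joint space minus border-zone cartilage the median differences were 0.3445 for MAPK targets, 0.3785 for chondrocyte genes and -0.6295 for interzone genes. They were -0.4686 for fibrous matrix, -0.087 for BMP and TGF-beta targets, -0.0317 for the hedgehog list, -0.1207 for matrix proteases and 0.2631 for endothelium. For inter-joint space minus inter-joint perichondrium they were -0.2977 for interzone genes, -0.1952 for fibrous matrix and 0.3729 for endothelium. For inter-joint perichondrium minus border-zone cartilage they were 0.265 for MAPK targets, -0.276 for interzone genes and -0.3048 for fibrous matrix. They were -0.09012 for the Wnt list and -0.1541 for the hedgehog list, whose shifts do not give the direction of pathway output. Without the reference types 148, 3 and 13 targets passed for these 3 differences, against 0, 0 and 0 by limma in the fit of all types, where 120, 21 and 22 had an unadjusted p below 0.05.

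Fibrous matrix and interzone lists were lower in GOF inter-joint space. Cartilage cells mixed into those regions are argued against as the whole cause, within the regions as drawn. The 71% share of cartilage that best gave the levels of 61 members predicted a chondrocyte list change of 1.58. The observed change was 0.1721 (0.0682 to 0.306 over the 4 pairs of animals). It was positive in each pair, so the test cannot exclude a smaller share of cartilage cells that accounts for part of the falls. Inter-joint space is tagged Sox9-low and regions were chosen with Sox9 staining, so the test cannot address cartilage cells elsewhere in the interzone. With the negative probe subtracted, the fibrous and interzone lists stayed lower, with adjusted p values of 4.22e-39 and 6.41e-13 by cameraPR. This argues against a different background as the whole cause. Those p values take targets as units and do not measure the spread between animals. A control animal of the other sex is argued against by adjusted p values of 6.2e-36 and 5.38e-13 without control replicate 1. The endothelial list was higher in the same contrast, with a median of 0.30 and 14 of 14 members positive (adjusted p = 0.000408, 0.00212 with an estimated correlation). The cause of the pattern stays open, a change in the share of vessel cells or of other cell types in the regions included. The space regions of the genotypes may also not match, since Sox9-high interzone was tagged apart as fusion in GOF knees alone. Both lists were lower in fusion regions than in control inter-joint space as well. How much the separate tagging adds to the difference was not tested.

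MAPK targets were higher in GOF inter-joint space, with a median of 0.52 (0.32 to 0.627 over the 4 pairs of animals). A general rise of stress genes from handling or fixation is argued against in inter-joint space. The 9 stress members outside the MAPK list had a median of -0.1311, with pairs from -0.371 to 0.122. The joint-region fit called 3 of them, Fosb, Jund and Jun, lower. Egr1, Fos, Ier2 and Junb are on both lists, so they cannot tell stress from MAPK signaling. The full stress list passed as higher in inter-joint perichondrium and over all region types. With the negative probe subtracted, the MAPK list stayed higher, with an adjusted p of 2.57e-20 by cameraPR, which takes targets as units. This argues against a different background as the whole cause. The cause of the pattern stays open. Litter, section or sex differences between the 4 animals, a change in the mix of cell types and the separate tagging of fusion regions were not tested for it.

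In fusion regions, cartilage genes were higher than in GOF inter-joint space and fibrous matrix genes were higher than in both GOF cartilage and GOF inter-joint space. A mixture of those tissues would keep each gene at or below its highest source. The median difference of the fibrous list from the higher of cartilage and space was 0.1514, with 0.275 in replicate 1 and 0.0275 in replicate 2, and 25 and 17 of 33 members above both. Both values lie above 0, but the mean is smaller than the spread between the 2 animals, so the mixture stays open. With perichondrium as a further source the median was 0.1235, with 0.255 and -0.00791, and a mixture may still account for the pattern.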

How the results depend on the processing

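Alternatives added after the data were seen were the fit without the reference types, the weights, the subtracted negative probe, perichondrium without its interzone-tagged regions, edgeR on recovered counts and the floored correlation. Over named genes, 894 of 1145 values under alternatives fixed before the data were seen kept direction and side of the threshold, 248 lost the call, 1 gained it and 2 reversed, and of 335 under added ones 310, 22, 3 and 0 did. Over lists the counts were 360, 73, 0 and 1 of 434 for those fixed earlier and 169, 25, 0 and 1 of 195 for added ones. The cause was not tested for the changes below, except that leaving out an animal leaves 1 sample in its group, assumed to vary like the other groups, and that taking only the genes above the median level tests fewer.

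Counts of calls moved by over 1.5 times as follows, with the count of the fit of all types in brackets. With a pseudocount of 0.1, fusion against GOF cartilage had 0 [2], and with a pseudocount of 5 border-zone cartilage had 3 [1]. With only the genes above the median level, border-zone cartilage had 2 [1], reference cartilage 739 [1422] and reference mesenchyme 84 [165]. With quantile normalization, border-zone cartilage had 2 [1], inter-joint space 58 [20, all shared], reference cartilage 775 [1422], reference mesenchyme 64 [165], fusion against GOF cartilage 1 [2] and control border-zone cartilage 125 [75]. With median centring, fusion against GOF space had 12 [43] and against GOF cartilage 1 [2]. Without trend, perichondrium had 1 [3], inter-joint space 10 [20], fusion against control space 78 [141], against GOF space 2 [43], against GOF cartilage 0 [2] and all region types 6 [44]. With control animals alone, control perichondrium had 8 [36] and control reference mesenchyme 777 [1268].

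The split of higher and lower calls moved by over 10 points with quantile normalization in reference cartilage (415 and 360 against 602 and 820), in perichondrium (3 and 1 against 3 and 0), in control inter-joint space (261 and 114 against 169 and 122), for fusion against control space (84 and 111 against 79 and 62) and for fusion against GOF space (40 and 23 against 34 and 9). With median centring it moved in reference mesenchyme (107 and 61 against 71 and 94) and over all region types (29 and 21 against 21 and 23). With only the genes above the median level it moved in reference mesenchyme (53 and 31), and with a pseudocount of 5 in inter-joint space (5 and 25 against 6 and 14) and over all region types (22 and 38). With the negative probe subtracted it moved in reference cartilage (862 and 771), reference mesenchyme (168 and 62), over all region types (45 and 27) and for fusion against control space (66 and 31).

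Without control replicate 1 the split was 608 and 369 in reference cartilage and 14 and 25 over all region types, and without control replicate 2 it was 407 and 108 in reference mesenchyme. Without GOF replicate 1 it was 633 and 1446 in reference cartilage, 156 and 412 in reference mesenchyme and 28 and 9 for fusion against control space. Without GOF replicate 2 it was 50 and 93 over all region types. Fits with more calls moved it as well. In inter-joint space it was 212 and 309 without the reference types, 153 and 207 with edgeR and 211 and 263 with regions as units. For fusion against GOF space it was 525 and 360 without the reference types, 269 and 161 with weights, 258 and 161 with edgeR and 427 and 202 with regions as units. In reference mesenchyme edgeR gave 14 and 12. Other moves of over 10 points in the split of target calls had under 10 calls in 1 or both of the fits compared.

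With each region type alone, cartilage, perichondrium, space, reference cartilage and reference mesenchyme had 91, 223, 354, 6 and 2 calls. With regions as units they had 276, 453, 474, 7 and 5, and fusion had 972 against control space, 629 against GOF space and 243 against GOF cartilage (animal as a block, correlation 0.0119). Without the reference types the joint types had 41, 200 and 521, fusion 1007, 885 and 230, the differences 148, 3 and 13, and all region types 319. Without the interzone-tagged regions perichondrium kept its 3 calls and 9 lists, and in the joint-region fit it had 182 calls, 174 of them shared, with Gdf5 at -1.12, Lgr5 at -1.26 and Pamr1 at -1.48. With weights the 5 types had 145, 387, 343, 3 and 2 and fusion 823, 430 and 200. With the negative probe subtracted, space had 7, fusion against GOF space 22, against GOF cartilage 0 and all region types 72. With edgeR the 5 types had 31, 229, 360, 4 and 26, fusion 802, 419 and 72, and all region types 354.

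With the replicate block, fusion against GOF cartilage had 0 calls and all region types 117, and no other count moved by over 1.5 times. Animals share only a number: the correlation of same-numbered deviations was 0.0326 over all types, so the block pairs nothing.

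Leaving out 1 animal gave 1 to 2 calls in cartilage, 1 to 2 in perichondrium, 1 to 6 in space, 44 to 2079 in reference cartilage, 2 to 568 in reference mesenchyme, 32 to 41 for fusion against control space, 1 to 6 against GOF space, 0 to 0 against GOF cartilage and 39 to 327 over all region types. The 3 differences had 0 in each case by limma. Lists passing in space ranged from 7 to 14.

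With an estimated correlation 1 list passed in border-zone cartilage [6] and 3 for fusion against GOF space [7], and the floored correlation gave 1 and 3. Pdgfra, called in neither, ranged from -0.2672 (without GOF replicate 2) to 0.0142 (without GOF replicate 1) in inter-joint space, and from -0.2572 (without GOF replicate 1) to 0.1025 (without GOF replicate 2) for fusion against GOF space. The chondrocyte list test turned in border-zone cartilage without GOF replicate 1 (mean t -0.1467, adjusted p = 0.981, against -1.576 without GOF replicate 2) and over all region types without the reference types (mean t -0.3424, adjusted p = 0.969), where in both only the position relative to the mean of the other targets turned, and it lost its call over all region types without GOF replicate 1 (adjusted p = 0.239).

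Depth limits genes near the negative probe, whose median per animal lay between 2.29 and 3.06, and their fold changes are understated.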

Other observations

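Penk, which encodes the opioid precursor proenkephalin, rose in GOF inter-joint space from 16.3 ± 2.3 to 42.7 ± 0.88 (SD, n = 2; log2 fold change 1.28, adjusted p = 1.6e-10 by limma). It and the genes named here are from the joint-region fit and were chosen after their values were seen. Igfbp3, which encodes an IGF binding protein, rose from 31.5 ± 1.7 to 76.7 ± 25 (1.28), and the chemokine gene Cxcl14 from 11.6 ± 1.5 to 27.3 ± 13 (1.24). Igfbp3 and Cxcl14 did not pass in inter-joint perichondrium, but neither was among the 3 genes called for the difference between space and perichondrium. The orphan nuclear receptor gene Nr4a1 rose from 9.39 ± 0.81 to 21.6 ± 7.9 and Nr4a2 from 5.89 ± 0.012 to 15.1 ± 6.8.

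Members of the hedgehog list moved in both directions in inter-joint space, and the list did not pass (adjusted p = 0.0719). The transcription factor gene Gli1 rose from 9.91 ± 0.38 to 18.0 ± 0.83 (0.83) and the receptor gene Ptch1 from 21.2 ± 1.0 to 30.9 ± 4.4 (0.56), both standard readouts of the pathway, and the co-receptor gene Boc rose by 0.41. The co-receptor genes Gas1 (336 ± 5.4 to 167 ± 46, -1.06) and Cdon (-0.79) and the repressor gene Gli3 (-0.80) fell. In inter-joint perichondrium Gas1 and Cdon fell, and Gli1 and Ptch1 did not pass. Gli1 was not among the 3 genes called for the difference between space and perichondrium.

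Y-linked transcripts separated control replicate 1 from the other animals. Ddx3y had a mean of 14.3 in control replicate 1 and of 2.77, 3.17 and 2.52 in control replicate 2 and GOF replicates 1 and 2. Eif2s3y had 12.7 against 3.07, 2.94 and 2.26, and Kdm5d 6.31 against 2.20, 2.21 and 1.74.

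Haemoglobin transcripts varied between animals. Hbb-b1 read 34.6 ± 17 in control and 85.6 ± 48 in GOF inter-joint space, and the erythroid list did not pass (adjusted p = 0.480).

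With 1 region drawn at random per animal in border-zone cartilage, 20 draws gave between 2 and 426 calls, with a median of 94.5, against 1 with all regions. The other types stayed averaged over their regions and shared their spread, as in the setting that gave false calls for the reference types. The added calls therefore cannot be read as changes that averaging hides. The 4 animals can be split in too few ways for a share under 0.05. With each region type alone the real split gave 91, 223 and 354 calls in cartilage, perichondrium and space, and the highest of the other splits gave 0 by limma, with 863, 616 and 661 targets at an unadjusted p below 0.05 when split by number and 529, 601 and 443 when crossed. Over all region types the real split gave 44 and the highest other 1. Each of the other splits puts 1 GOF and 1 control animal in each group. A genotype difference would then widen the spread within groups, so their low counts cannot serve as a null for the real split.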
